A study of Mus musculus with 4 samples.

How the data were processed

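Visium spatial transcriptomes of 4 mouse brain hemisphere sections were used, 1 section for each of 4 genotypes. The deposited matrix holds raw UMI counts for 19090 genes in 10549 spots over tissue, and per the submitters' processing notes Space Ranger and Seurat were used with the mm10 build, with versions not given in the sources used here. The percent of mitochondrial counts per spot was deposited with the spot table. The other deposited columns give each spot's section, its region label at 2 levels (17 and 26 names), an expression cluster (22 in all), and marks for plaque spots and their neighbours. How regions, clusters and plaque marks were made is not given in the sources used here, and no region abbreviation was expanded. Total counts per section were between 26049860 and 36461389, and every interval below covers counting error only. Spots were not treated as replicates of a genotype, no doublet caller was run, and every deposited spot was kept. Intervals of shares of spots take spots as independent and do not cover clustering of spots.

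Counts were summed per section and scaled to the section total (CPM). A gene's summed count has an exact Poisson interval and each ratio an exact conditional binomial (Clopper-Pearson) interval at 95%, which cover counting error only. A count of 0 was set to a floor of 3 counts. Genes with a mean of at least 5 CPM entered lists and counts of genes (11033). For each of 24 gene lists the median log2 ratio was taken over its members, with its percentile among 10000 random lists of the same size matched in 20 bins of mean expression, and a binomial order-statistic interval for lists of at least 6 members. Random lists were drawn gene by gene, so a percentile does not cover correlation among list members or differences between sections. Counts of members higher or lower are of ratios not set against the median of all genes. Lists other than the segment leave out its genes, and a list used to check the transgenes is not reported here. Medians between sections are reported relative to the median of all genes, a choice made after values had been seen, because TMM factors moved that median by more than 0.1. Lists of T and B cells and border macrophages had 2 and 1 measured members. Regions were compared where every section held at least 30 spots (12 regions), and region-standardised levels weight regional CPM by the pooled share of spots. Standardising by label does not make the tissue within a label alike. For shares of spots with a gene, each spot was thinned to 4755 UMIs and shallower spots were left out (220, 196, 235 and 226 in wild-type, Dp16, 5xFAD and 5xFAD-Dp16), with exact binomial intervals. Clec7a was not analysed here.

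The Dp16 effect was read from Dp16 over wild-type and 5xFAD-Dp16 over 5xFAD, and the 5xFAD effect from 5xFAD over wild-type and 5xFAD-Dp16 over Dp16. The double difference is the log2 ratio of 5xFAD-Dp16 over Dp16 minus that of 5xFAD over wild-type. Gene positions came from RefSeq for GRCm38, the assembly of mm10, for 18043 genes matched by symbol. Plaque spots were compared with unmarked spots within regions holding at least 10 of each kind (10 and 11 regions).

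Genes were named by a rule written before the data were examined. For each effect these are the 10 highest and 10 lowest genes by the smallest of 4 log2 ratios, namely both pairs as whole sections and region-standardised. Segment genes were ranked apart (10 highest, 3 lowest). For the double difference the 5 highest and 5 lowest of at least 10 CPM were named, for each list the 3 most abundant members and the highest and lowest ratio, and a fixed set of genes always. For plaque marks, the 15 highest and 8 lowest by the smaller ratio of the 2 sections were named, a rule written after the marks had been seen.

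The ratio intervals and list percentiles were tested on simulated data: Poisson counts for the 11033 genes with 200 genes changed. For Dp16 over wild-type the interval held the true ratio for 95.2% of unchanged genes and for 94.0, 93.3 and 97.5% of genes changed by 1.5, 2 and 4-fold, and for 5xFAD-Dp16 over 5xFAD for 95.0% and for 92.0, 98.3 and 92.5%. Segment members raised 1.5-fold lay at percentile 100 in each. The simulated counts follow the Poisson model that the intervals assume. The simulation therefore checks the calculation and does not cover differences between sections or correlated genes.

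Alternatives fixed before the data were examined were TMM factors, leaving out mitochondrial, ribosomal protein and haemoglobin genes, region-standardised levels, the mean over spots, spots of at least 1000 UMIs, thresholds of 1 and 20 CPM, a 2-fold threshold, unthinned shares, shares at 2 UMIs, shares standardised by region, and regions of at least 100 spots. Added later were the segment by coordinates, leaving out expression cluster 21, leaving out clusters 12 and 13, leaving out the region labelled Hypothalamus, and unmatched plaque sums. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 for TMM factors.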

Results

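Spatial gene expression was measured with Visium, in which an array of barcoded spots captures the RNA of the tissue lying above each spot, so that a spot can hold parts of several cells. The samples were 4 brain hemisphere sections, 10 µm thick and cut between bregma 1 and -2 mm, from male mice aged 9 months. Each genotype had 1 section: wild-type, Dp16, 5xFAD and 5xFAD-Dp16. Dp16 mice carry a duplication of the part of chromosome 16 that is orthologous to much of human chromosome 21, and 5xFAD mice carry human transgenes with familial Alzheimer's disease mutations and form amyloid plaques. The sections held 2721, 2540, 2347 and 2941 spots in that order, with totals of 34361244, 30885159, 26049860 and 36461389 UMIs and medians of 11639, 10448.5, 9404 and 11144 UMIs per spot. With 1 section per genotype no comparison had a replicate check, and no p-value was computed. Ratios are log2 values of CPM, a gene's UMIs scaled to the total of its section, with exact intervals that cover counting error only. These intervals excluded 0 for 62.6% of the 11033 genes of at least 5 CPM between Dp16 and wild-type, and for 41.9% between 5xFAD-Dp16 and Dp16, so differences between sections exceeded counting error for many genes. Each effect was therefore read in 2 pairs that share no section. List medians between sections are given relative to the median of all genes, which lay at -0.16 between 5xFAD-Dp16 and wild-type and at -0.047 with TMM factors.

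The first question was whether the sections carried the genotypes on their labels. Genes of the duplicated segment (chromosome 16, 75540514 to 97962627, mm10) were higher in both sections with the duplication, by a relative list median of 0.54 for Dp16 over wild-type and 0.58 for 5xFAD-Dp16 over 5xFAD, where a log2 of 0.585 is a fold of 1.5. Of the 71 measured members, 68 were higher in both pairs and 56 were higher beyond counting error in both. Ratios of single genes between sections are not set against the median of all genes, which lay at -0.13 and -0.073 in these pairs. Mrps6, a mitochondrial ribosomal protein, was at 87.5 CPM in wild-type and 173 CPM in Dp16 (log2 0.99, and 0.84 in the second pair). Ifnar2, a subunit of the type I interferon receptor, had log2 ratios of 0.87 and 0.70, and Atp5j, a subunit of ATP synthase, 0.73 and 0.71. The list's median lay at percentile 100 of matched random lists in both pairs.

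Other receptor and dosage-sensitive genes of the segment spanned a wide range. The interferon receptor genes Ifnar1 (0.33 and 0.65) and Ifngr2 (0.37 and 0.89) and the interleukin-10 receptor subunit Il10rb (0.86 and 0.58) were higher in both pairs. Rcan1, an inhibitor of calcineurin, had 0.48 and 0.76, and the kinase gene Dyrk1a 0.20 and 0.37. Sod1, a superoxide dismutase, had 0.62 and 0.26, and the nucleosome-binding Hmgn1 0.54 and 0.83. App, the mouse amyloid precursor protein gene, had 0.18 and 0.31. Set against the median of all genes, as the list is, Dyrk1a had 0.33 and 0.44 and App 0.31 and 0.39. The oligodendrocyte transcription factors Olig1 (0.12 and 0.32) and Olig2 (0.35 and 0.21) were among the smaller ratios, with Ttc3 (0.26 and 0.36), Itsn1 (0.31 and 0.42), Son (0.28 and 0.24) and Usp16 (0.48 and 0.15). The 3 lowest in the segment, by the smallest of the whole-section and region-standardised ratios, were Clic6 (2.34 and -0.04), Kcne2 (2.79 and 0.25) and Pcp4 (-0.19 and 0.51). Clic6 and Kcne2 are choroid plexus genes, and the choroid plexus list had relative medians of 1.60 and -0.054 in the same pairs (region-standardised 0.49 and -0.50).

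The rest of the chromosome did not share the difference as a group. The 72 genes that RefSeq places inside it had relative folds of 1.455 and 1.498, and the 278 genes on the rest of chromosome 16 had relative medians of 0.0031 and 0.0064. Windows of 5 Mb were kept where they held at least 8 genes, which left out parts of the segment and of the genome. The 3 kept inside the segment ranged from 0.49 to 0.61 and from 0.49 to 0.62. Among the 421 kept elsewhere the largest absolute value was 0.27 and 0.17. All 12 compared regions showed the list above the median of all genes in both pairs, from 0.43 to 0.62 and from 0.48 to 0.62. Between sections with equal copies of the segment the list lay at 0.019 and 0.044. A list of 56 control genes of chromosome 16 outside the segment had -0.045 and -0.020 in the Dp16 pairs, with 18 members lower and 2 higher beyond counting error in both, and -0.046 and -0.014 in the 5xFAD pairs.

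**Figure D1:**
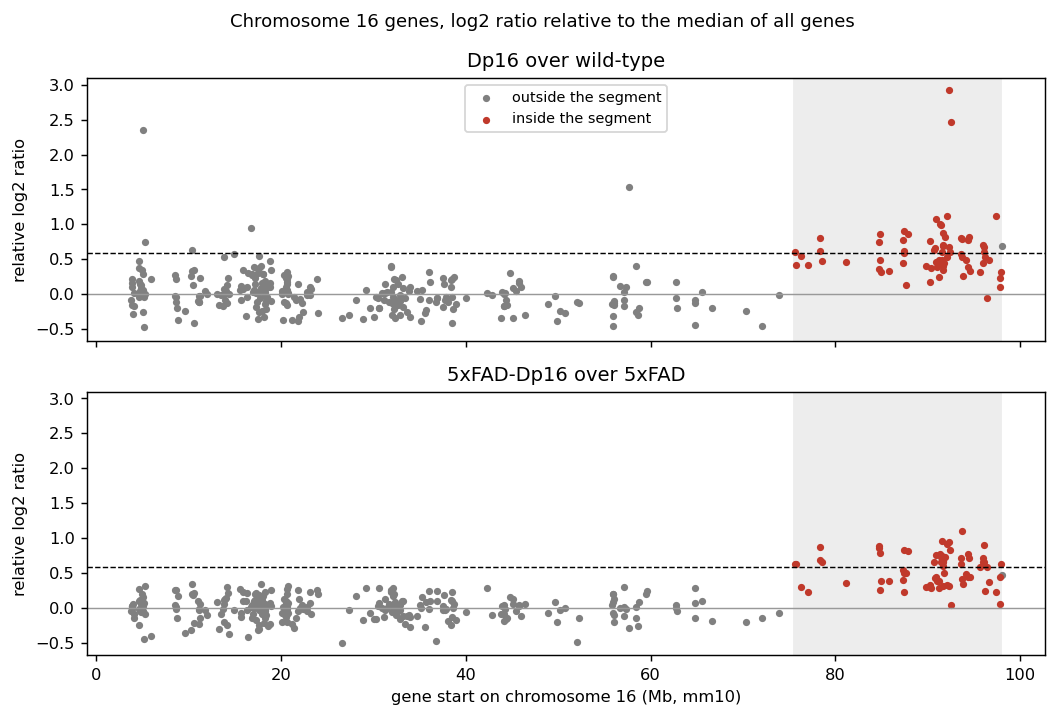
Log2 ratio of each chromosome 16 gene relative to the median of all genes (y axis) against gene start in Mb (x axis), for Dp16 over wild-type (upper panel) and 5xFAD-Dp16 over 5xFAD (lower panel). Red points are the 72 genes in the duplicated segment (shaded), grey points the other genes of the chromosome, and the dashed line marks 0.585, a fold of 1.5.

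The 5xFAD label was checked with Thy1, whose regulatory elements drive the transgenes. Thy1 was at 562 CPM in wild-type, 477 in Dp16, 1449 in 5xFAD and 1186 in 5xFAD-Dp16, with log2 ratios of 1.37 and 1.32. Mouse App had -0.14 and -0.0036. The counts were made against a mouse build, so human transgene transcripts were not measured as such.

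The effect of the 5xFAD transgenes was read without and with the duplication. Counts of list members beyond counting error are of ratios with the median of all genes not taken off. Of all 11033 genes, 4037 and 2658 were lower and 1406 and 1968 higher beyond counting error in these pairs. Plaque-associated microglial genes were higher in both pairs, with relative list medians of 0.86 for 5xFAD over wild-type and 0.57 for 5xFAD-Dp16 over Dp16, both at percentile 100 of matched random lists. The second value was 0.92 without the spots of expression clusters 12 and 13, which meningeal, smooth muscle, pituitary and choroid plexus genes lead. Of 43 members, 36 were higher and 1 was lower beyond counting error in both pairs. Cst7, which encodes the protease inhibitor cystatin F, was at 0.611 CPM in wild-type and 0.130 in Dp16 against 83.8 in 5xFAD and 74.98 in 5xFAD-Dp16. The lipid-sensing receptor Trem2 had log2 ratios of 2.02 and 2.08, its adaptor Tyrobp 1.78 and 1.73, and the integrin Itgax 5.07 and 4.78. The chemokines Ccl3 (3.27 and 4.49) and Ccl6 (3.04 and 2.97), the glycoprotein Gpnmb (2.79 and 2.08), Cd52 (2.14 and 1.94) and the lysosomal Cd68 (1.62 and 1.63) were also among the 10 highest genes, with Bcl2a1b (2.55 and 1.505) and the Fc receptor Fcgr2b (1.64 and 1.45). Apoe, the main brain apolipoprotein, had 0.38 and 0.0071.

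Other immune lists were higher in both pairs, except the MHC list, which was within matched lists in the second. Complement genes had relative medians of 1.09 and 1.09, with C1qa at 1.07 and 1.09 and C4b at 1.44 and 1.10, and 4 of 6 members were higher beyond counting error in both pairs. Homeostatic microglial genes had 0.40 and 0.44, with 10 of 16 members higher beyond counting error in both. MHC and antigen presentation genes had 0.73 and 0.082, the second at percentile 89.9 and being 0.44 without clusters 12 and 13 and -0.0021 without the region labelled Hypothalamus, with B2m, the light chain of class I molecules, at 0.73 and 0.79 and H2-D1 at 0.57 and 0.75. Interferon-stimulated genes had 0.37 and 0.42, with 4 of 11 higher beyond counting error in both. Reactive astrocyte genes had 0.42 and 0.19, and 6 of 12 members were higher beyond counting error in both: Gfap, the astrocyte intermediate filament, had 1.48 and 0.91, and Serpina3n, a protease inhibitor, 1.19 and 0.77. General astrocyte markers lay at -0.017 and -0.051.

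Synaptic and glutamatergic genes lay slightly below the median of all genes, at -0.14 and -0.10, with 17 of 30 lower beyond counting error in both pairs and 1 higher. Inhibitory neuron markers had -0.23 and 0.0076, with 7 of 16 lower beyond counting error in both, and genes of oligodendrocytes and myelin -0.078 and 0.0055. Region-standardised, the inhibitory list had -0.24 and -0.11 and the oligodendrocyte list 0.13 and 0.24. Nuclear genes of oxidative phosphorylation had 0.14 and 0.038, with 16 of 55 higher beyond counting error in both, but the second lay at percentile 3.015 of matched random lists, low for genes of this abundance. Cholesterol synthesis genes had 0.069 and 0.13, heat shock and unfolded protein genes 0.055 and 0.036, and oligodendrocyte precursor genes -0.16 and -0.14. Markers of vessels (0.11 and -0.18), meninges (0.61 and -0.53), choroid plexus (1.155 and -0.87) and blood (-0.069 and 0.78) took opposite signs in the pairs. Immediate early genes also did, at -0.29 and 0.31, and so did T and B cell genes (2 measured, -0.097 and 0.33). Dab2, the single measured marker of border macrophages, did so as well, with list values of 1.00 and -0.53. Under some alternatives the first value took the other sign for vessels (reaching -0.0078), blood (0.058) and T and B cell genes (0.28).

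Counting genes of at least 5 CPM, 47 were at least 1.5-fold higher in both 5xFAD pairs, where 2.54 would arise from independent lists, and 28 of them belonged to the microglial, complement or MHC lists. Only 4 were lower by as much in both, against 1.28: the neuropeptide genes Avp (-3.28 and -2.94) and Oxt (-3.83 and -2.84), Arhgef26 (-1.36 and -1.31) and Gm43305 (-1.31 and -2.07). Without the region labelled Hypothalamus, Arhgef26 and Gm43305 remained, while Avp had -1.90 and -0.019 and Oxt 0.95 and -0.48. The next lowest by the rule were Dlk1 (-0.83 and -0.57), Grin2d (-0.75 and -0.53), Rnf182 (-0.72 and -0.44), Phtf2 (-0.62 and -0.49), Brsk1 (-0.50 and -0.53) and Sfi1 (-0.43 and -0.71). Across all genes, which are not replicates, the pairs had a Pearson r of -0.010 and a Spearman rho of 0.14.

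**Figure D2:**
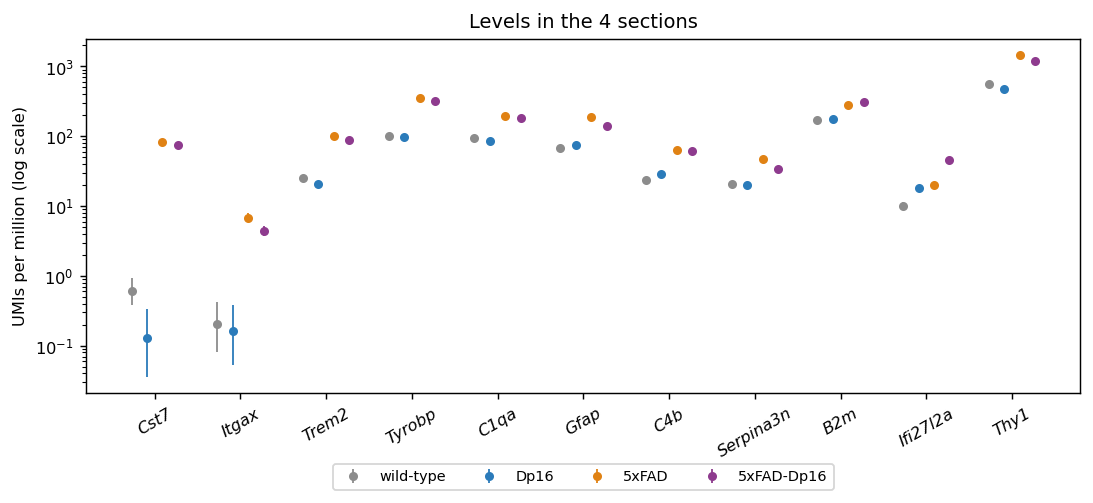
CPM (y axis, log scale) of 11 genes in each of the 4 sections, with exact 95% Poisson intervals that cover counting error. Cst7 and Itgax lie under 1 CPM in wild-type and Dp16, and at 83.8 and 6.83 CPM in 5xFAD.

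The response was spread over the section rather than held in a single region. After thinning each spot to 4755 UMIs, 20.4% of 5xFAD spots (95% interval 18.7 to 22.1) and 17.4% of 5xFAD-Dp16 spots (16.01 to 18.9) had a UMI of Cst7 or Itgax, against 0.360% in wild-type and 0.0853% in Dp16. For Trem2 the shares were 29.4% and 26.3% against 11.8% and 9.47%. The plaque-associated list was above the median of all genes in 11 of 12 regions for 5xFAD over wild-type, the exception being VL, a region led by the choroid plexus genes Kcne2 and Ecrg4, at -0.25. It was above in all 12 for 5xFAD-Dp16 over Dp16.

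Gene lists outside the segment were read for the Dp16 effect in the same way. Here too, counts of members are of ratios with the median of all genes not taken off. Of all 11033 genes, 5329 and 3617 were lower and 1580 and 1641 higher beyond counting error in these pairs. How many were so in both pairs was not counted. Oxidative phosphorylation genes were higher in both pairs, with relative medians of 0.26 and 0.16, and 41 of 55 members were higher beyond counting error in both. Matched random lists shared part of this: before the median of all genes was taken off, the list had 0.13 and 0.089 and matched lists 0.019 and 0.039, and region-standardised the second pair lay at percentile 85.7. Synaptic genes were lower, at -0.15 and -0.10, with 23 of 30 lower beyond counting error in both, and homeostatic microglial genes lay at -0.22 and -0.091, the second within matched lists (percentile 5.89, and 34.8 region-standardised). Plaque-associated microglial genes had 0.16 and -0.060, complement genes 0.22 and 0.011, MHC genes 0.44 and 0.076, and reactive astrocyte genes 0.11 and 0.051. Without clusters 12 and 13 the first values of these lists were 0.040, -0.0068, 0.20 and 0.0100. Astrocyte markers had 0.025 and -0.027. Oligodendrocyte genes had -0.17 and -0.026, with 10 of 24 lower beyond counting error in both (region-standardised -0.025 and 0.088), precursors -0.038 and -0.15, inhibitory neurons -0.094 and 0.13, cholesterol synthesis -0.053 and -0.045, heat shock -0.0072 and -0.068, and vessels 0.20 and 0.020. T and B cell genes had -0.41 and 0.018, and the border macrophage marker 1.12 and -0.42.

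Interferon-stimulated genes had relative medians of 0.31 for Dp16 over wild-type and 0.43 for 5xFAD-Dp16 over 5xFAD, but the pairs parted when tissue was taken into account. Spots of expression clusters 12 and 13, led by the pituitary hormone gene Cga, the meningeal genes Myoc and Slc6a13, the smooth muscle genes Acta2 and Tagln, and the choroid plexus genes Kcne2 and Ttr, made up 2.46% of the wild-type section and 5.83, 6.01 and 6.22% of Dp16, 5xFAD and 5xFAD-Dp16. Without them the median was -0.025 in the first pair (percentile 46.4) and 0.46 in the second (percentile 100). Ifi27l2a, an interferon-induced gene, went from 0.83 to -0.20 in the first pair and from 1.21 to 1.36 in the second, and Bst2, which encodes tetherin, from 0.67 to 0.03 and from 0.27 to 0.54. Ifit3 kept ratios of 0.47 and 0.54, against 0.40 and 0.50 with all spots. Bst2 was named after its values had been seen.

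Immediate early genes, which neuronal activity induces, were lower in Dp16 than in wild-type by a relative median of -0.71, and by -0.084 in 5xFAD-Dp16 over 5xFAD. The transcription factor gene Egr1 was at 143 CPM in wild-type and 64.9 in Dp16 (log2 -1.14, and -0.05 in the second pair), and the postsynaptic Homer1 had -0.62 and -0.12. Haemoglobin and other blood genes had -1.21 and -0.15, and meningeal markers 0.98 and 0.15. Over the alternatives the second values ranged from -0.49 to 0.062 for blood and from -0.40 to 0.17 for meningeal markers. Ttr, the choroid plexus transthyretin gene, took 0.680% of UMIs in wild-type and 3.21% in Dp16.

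Outside the segment, 2 genes were at least 1.5-fold higher in both Dp16 pairs, AW495222 (0.60 and 0.60) and Ifi27l2a, against 0.796 from independent lists, and 16 were lower, against 2.75. The highest by the rule were BC039966 (1.41 and 0.53), the smooth muscle gene Tagln (0.60 and 0.49, the first being -0.33 without clusters 12 and 13), the Notch ligand Dll3 (0.43 and 0.56), Nme4 (0.45 and 0.58), Vwf (1.02 and 0.51), which encodes von Willebrand factor, Snhg4 (0.38 and 0.39) and Gm16701.1 (0.43 and 0.54). B230307C23Rik (0.56 and 0.40) lies on chromosome 16 at 97997078 to 98016756, just beyond the end of the segment as taken here. The lowest was Gm5741, with 361 and 490 UMIs in wild-type and 5xFAD and 2 and 3 UMIs in Dp16 and 5xFAD-Dp16 (log2 -7.34, counting interval -10.39 to -5.48, and -7.84, -10.12 to -6.28), followed by the G protein subunit Gng8 (-2.05 and -2.53), the immunoglobulin gene Igkc (-1.12 and -3.69) and the neuropeptide gene Tac2 (-1.27 and -1.06). Lrrc55 (-1.05 and -0.95), Syt6 (-0.81 and -1.06), Syt9 (-1.08 and -0.83), Catsperz (-0.73 and -0.79), Sdk2 (-0.81 and -0.68) and Ccn1 (-0.75 and -0.85) completed the 10. Gm5741, Gng8 and Tac2 lead expression cluster 21, which held 15 spots in wild-type, 20 in 5xFAD and 0 in both other sections. Without that cluster, 9 of the 16 genes were still lower by 1.5-fold in both pairs. Across genes outside the segment the pairs had a Pearson r of 0.037 and a Spearman rho of 0.33.

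**Figure D3:**
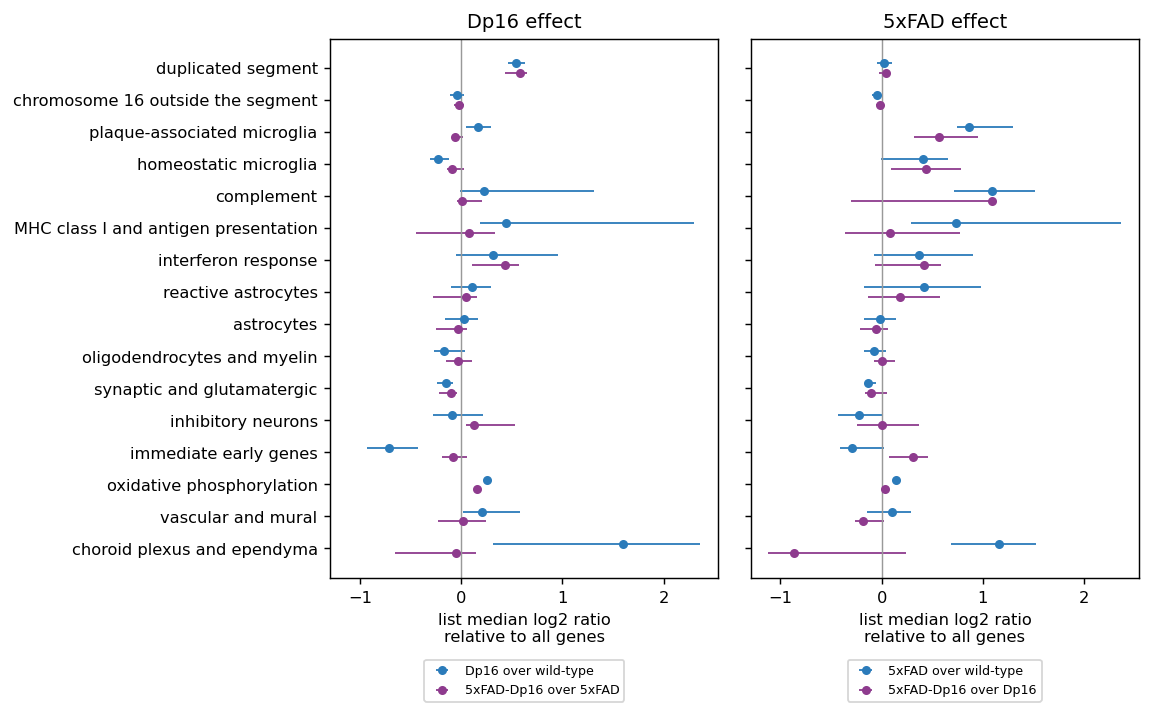
Median log2 ratio of each gene list relative to the median of all genes (x axis), for the Dp16 effect (left) and the 5xFAD effect (right), with 1 point per pair and binomial order-statistic intervals over list members. The duplicated segment lies at 0.54 and 0.58 on the left, and plaque-associated microglia at 0.86 and 0.57 on the right.

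The combined genotype was set against wild-type as values, since it shares its sections with the comparisons above. Between 5xFAD-Dp16 and wild-type, plaque-associated microglial genes had a relative median of 0.91, complement 1.10, MHC genes 1.00, interferon-stimulated genes 0.90, the duplicated segment 0.56 and synaptic genes -0.26. Ifi27l2a was at 10.2 CPM in wild-type and 46.1 CPM in 5xFAD-Dp16, a fold of 4.54, against folds over wild-type of 1.77 in Dp16 and 1.97 in 5xFAD.

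Whether the 5xFAD effect was larger or smaller with the duplication was read from the difference of its log2 ratios in the 2 pairs. The plaque-associated list had a relative median difference of -0.24, interferon-stimulated genes 0.13, complement -0.22, MHC genes -0.29, homeostatic microglia 0.13 and immediate early genes 0.70. The plaque-associated value was -0.10 with levels standardised to the same regional make-up. The interferon value was -0.38 with members of at least 20 CPM, and the complement and MHC values were 0.0026 and -0.047 as means over spots. Trem2 differed by 0.06 and Tyrobp by -0.05. Among genes of at least 10 CPM the highest differences were those of Pmch, Hcrt, Cartpt and Pomc, which encode hypothalamic neuropeptides, and of Lbhd2. Pmch was at 1419 CPM in wild-type and 0.712, 0.653 and 9.27 CPM in Dp16, 5xFAD and 5xFAD-Dp16. The lowest were Ctxn3 (-3.08), Cox8b (-2.98), Igkc (-2.57, but 0.88 without clusters 12 and 13), the MHC class II invariant chain Cd74 (-2.48) and Myoc (-2.45). Expression cluster 15, led by Hcrt, Pmch and Pomc, had 228 spots in wild-type, 0 in Dp16, 0 in 5xFAD and 1 in 5xFAD-Dp16, and cluster 17, led by Ctxn3, had 0, 39, 55 and 52.

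Spots that carry the authors' plaque mark were compared with unmarked spots of the same region within each section, a comparison added after the marks had been seen. How the marks were made is not given in the sources used here. In 5xFAD, 324 of 2347 spots (13.8%) were marked, and in 5xFAD-Dp16 396 of 2941 (13.5%). All 43 plaque-associated microglial genes were higher in marked spots in both sections, with medians of 1.11 and 0.98, where the median of all genes, not taken off in this comparison, was -0.020 and 0.0079. Cst7 had 2.72 and 2.49, Gpnmb 3.30 and 2.42, Trem2 1.92 and 1.93, and Tyrobp 1.71 and 1.65. The cytokine Spp1 (2.33 and 1.47), Wfdc17 (2.14 and 2.14), Ccl6 (2.04 and 1.64), Ccl3 (1.96 and 1.69), the growth factor Igf1 (1.95 and 1.40), Cd68 (1.81 and 1.40) and lysozyme Lyz2 (1.76 and 1.58) were among the 15 highest. In spots marked as neighbours of plaques the list's median was 0.46 and 0.30.

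Complement genes (1.05 and 1.10), MHC genes (1.01 and 0.93), homeostatic microglial genes (0.55 and 0.77) and interferon-stimulated genes (0.41 and 0.40) were also higher in marked spots. Reactive astrocyte genes had medians of 0.145 and 0.095 and astrocyte markers -0.12 and -0.17. With sums not matched by region, reactive astrocyte genes had 0.036 and -0.036, interferon-stimulated genes 0.19 and 0.42, and MHC genes 0.82 and 0.49. Synaptic genes lay at -0.027 and -0.033, and oligodendrocyte genes at 0.020 and 0.27. Meningeal genes (-1.005 and -1.09) and choroid plexus genes (-0.79 and -0.65) were lower in marked spots, and immediate early genes had 0.028 and -0.24. The lowest genes were Ecel1 (-2.20 and -2.84), Igkc (-3.15 and -1.70), the calcium-binding Calb2 (-2.01 and -1.70) and neuroglobin Ngb (-2.23 and -2.19), with AW551984 (-1.64 and -1.65). The rule also named Pifo, Krt18 and Igha, whose counts in marked spots of 5xFAD-Dp16 were too low for a firm value: Pifo had -1.64 and -3.61 (counting interval of the second -6.47 to -0.75), Krt18 -1.64 and -2.81 (-5.68 to 0.066), and Igha -3.26 in 5xFAD and no UMI in marked spots of 5xFAD-Dp16 within the matched regions. Across genes the sections had an r of 0.42. In marked spots of both, 122 genes were at least 1.5-fold higher, against 6.60 from independent lists, and 141 were lower by as much, against 20.03.

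**Figure D4:**
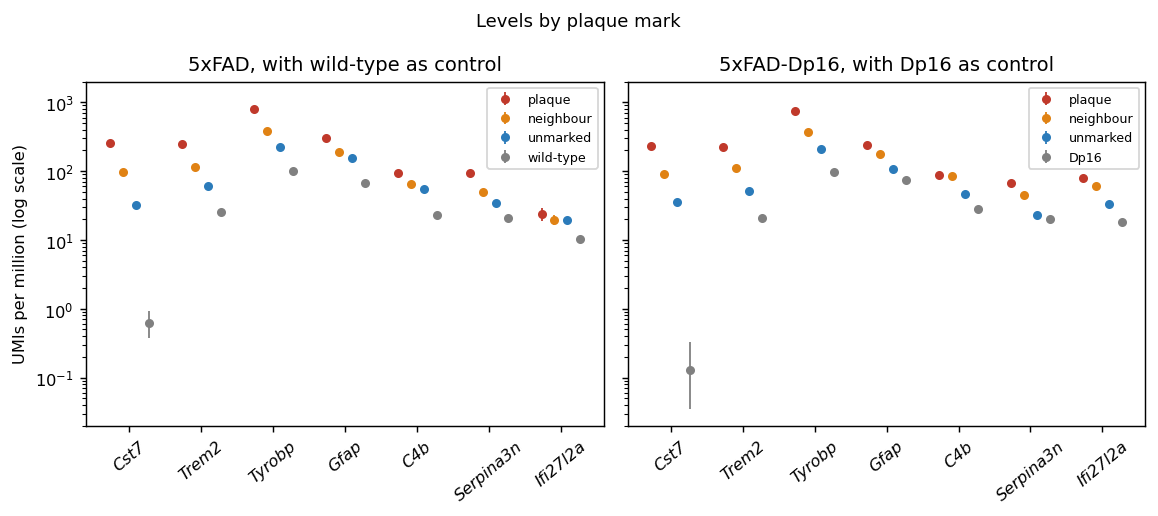
CPM (y axis, log scale) of 7 genes in spots marked as plaque, in neighbour spots, in unmarked spots and in the section without transgenes, with exact 95% Poisson intervals. Levels are sums over all spots of a kind and are not matched by region. Cst7 is at 260 CPM in plaque spots, 98.8 in neighbours and 32.6 in unmarked spots of 5xFAD, against 0.611 in wild-type.

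Summed over all spots of a kind and not matched by region, Ifi27l2a was at 23.6 CPM in marked and 19.3 CPM in unmarked spots of 5xFAD. In 5xFAD-Dp16 it was at 80.0 and 33.7 CPM. A UMI of Cst7 or Itgax was found in 47.0 and 44.7% of marked spots, 26.4 and 22.0% of neighbours and 11.1 and 9.25% of unmarked spots after thinning. In the region labelled Hippocampus, led by Spink8 and Hpca, 5.42% of 240 spots were marked in 5xFAD (95% interval 2.92 to 9.09) and 15.96% of 307 in 5xFAD-Dp16 (12.1 to 20.5). In the region labelled Hypothalamus the shares were 22.6% (17.9 to 27.9) and 10.9% (8.26 to 13.99). These intervals take spots as independent and cover neither clustering of marks nor differences between sections. Tissue under the Hypothalamus label also differed: expression cluster 16, found mainly there, had 5 spots in 5xFAD and 88 in 5xFAD-Dp16. The cortical regions labelled SSp (16.3 and 27.4%) and PTL (15.4 and 26.4%) had larger shares in 5xFAD-Dp16, and OLF (15.1 and 7.46%) a smaller share.

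**Figure D5:**
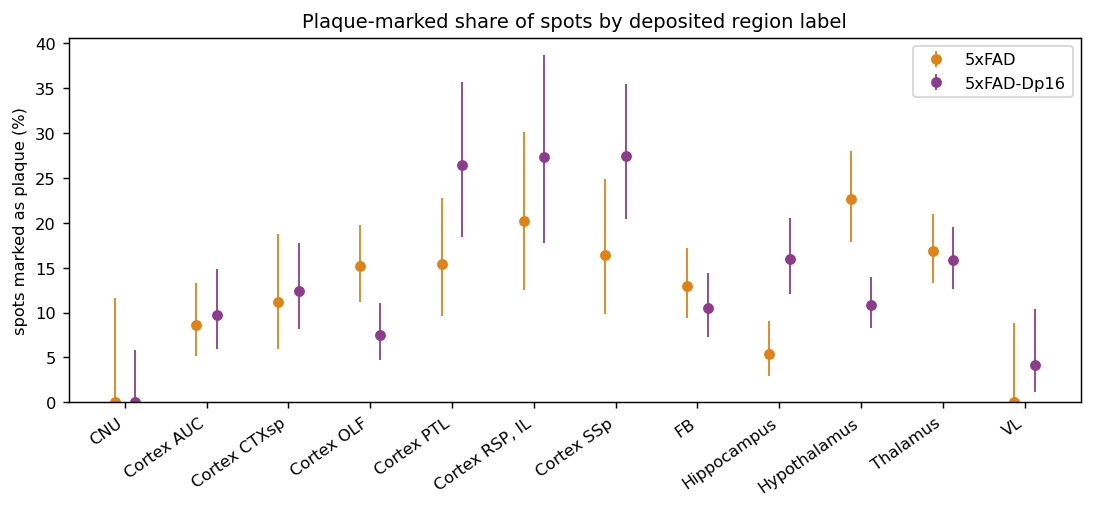
Percent of spots marked as plaque (y axis) in each of the 12 compared regions (x axis, labels as deposited) of the 5xFAD and 5xFAD-Dp16 sections, with exact 95% binomial intervals that cover counting error. The intervals take spots as independent. Hippocampus lies at 5.42 and 15.96%, and Hypothalamus at 22.6 and 10.9%.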

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

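The tests on clumping of Cst7 and of Tyrobp for deposits were chosen before their results were seen. The test on clusters 12 and 13 was chosen after other values of the data had been seen but before its own result. The other tests in this part were chosen after the result was seen, and so were reading the clusters 12 and 13 test for each pair on its own, using it for other results, and setting Tyrobp against an even spread. Differences between pairs were not tested, since each rests on 1 section per genotype.

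Lists of at least 3 measured members whose relative medians took opposite signs in the 2 pairs of an effect, each outside the central range of matched lists, were these. Plaque-associated microglial genes had 0.16 and -0.060 in the Dp16 pairs, a difference of -0.22, but both were positive when region-standardised (0.087 and 0.027), and the first was 0.040 without the spots of clusters 12 and 13. Immediate early genes had -0.29 and 0.31 in the 5xFAD pairs, a difference of 0.60. Meningeal genes had 0.61 and -0.53, a difference of -1.14, and choroid plexus genes 1.155 and -0.87, a difference of -2.02. By the same rule on medians not set against all genes, blood genes in plaque over unmarked spots had 0.55 in 5xFAD and -0.76 in 5xFAD-Dp16, a difference of -1.31.

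Interferon-stimulated genes were higher in both Dp16 pairs with all spots. Without the spots of clusters 12 and 13 the relative median was -0.025 for Dp16 over wild-type and 0.46 for 5xFAD-Dp16 over 5xFAD. More tissue of these clusters, meningeal and choroid plexus tissue among it, may thus account for the first pair and was argued against for the second. More resting microglia would need homeostatic microglial genes to be higher as well, and these lay at -0.22 and -0.091, the second within matched lists. That list holds genes of resting microglia, so it cannot decide whether other microglia were more numerous. The segment itself, which holds interferon receptor genes, stays open as an untested explanation of the second pair.

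Immediate early genes were lower in the Dp16 section than in wild-type. A scale factor moves every gene alike, and the list lay at -0.71 relative to all genes. Different shares of the region labels were argued against by 11 of 12 regions showing the list below all genes, Hippocampus at 0.037 being the exception. Tissue within a label was not alike, so its make-up stays open. Clusters 0 and 7, found most often under the label Cortex OLF, had 97 and 316 spots in wild-type and 390 and 107 in Dp16. An equal effect of the duplication with and without the transgenes was left open. The second pair had -0.084 and the first an interval of -0.93 to -0.43, but that interval covers list members and not sections. How animals or tissue were handled could act on these genes, was not given in the sources used here, and cannot be separated from genotype with 1 section each.

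Unmarked spots of the 5xFAD sections held plaque-associated genes above the control sections. Spots with at least 3 Cst7 UMIs were 3.56 and 1.86 times the Poisson number, so the bound of 2 set beforehand was missed in 5xFAD-Dp16, but Tyrobp in those spots was 6.61 and 8.52 times that of other unmarked spots, which argues against RNA spread evenly. Spread from the plaque spots alone was left open. Tyrobp in the unmarked spots chosen by Cst7, at 1203 and 1426 CPM, was above the mean of plaque spots (803 and 750). It was near that of neighbour spots with at least 3 Cst7 UMIs (1282 and 1424) but below such plaque spots (1600 and 1711). The highest over lowest percent of the plaque excess was 1.45 and 1.16 for Cst7, Trem2 and Tyrobp. The percent of Gfap, C4b and Serpina3n together over that of these microglial genes was 2.04 and 1.43. Serpina3n alone had 20.9 and 12.4% of its plaque excess, against 17.8 and 18.7% for the microglial genes together. Control levels came from another section, whose differences counting error does not cover. Deposits in unmarked spots may contribute, since they need the Tyrobp ratios seen, but microglia gathered without a deposit would give the same ratios.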

How the results depend on the processing

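Leaving out cluster 21, clusters 12 and 13 or the region labelled Hypothalamus, the segment by coordinates and unmatched plaque sums were chosen after values had been seen, as were the limits used to call a value moved. The other alternatives were chosen before the data were examined. No paired analysis was possible because each genotype has 1 section and no result comes from a test. Of 1436 list values, 1334 stayed within the interval of the reported median. Of 3616 gene values, 2690 stayed within counting error. Among gene values reported at 1.5-fold or more, 4 changed sign, and sign changes of smaller ratios were not counted. The segment in its pairs (0.54 to 0.58 and 0.52 to 0.60) and the plaque-associated list in its pairs (0.82 to 1.00 and 0.52 to 0.94) kept their direction under every alternative run. The interferon list for Dp16 over wild-type went from 0.31 to -0.025 without clusters 12 and 13, inside its wide interval. Its highest value under any alternative was 0.87. Depth limits Cst7 and Itgax in the sections without transgenes.

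The cause of the following changes was not tested, except where fewer genes or a stricter threshold make it plain. The plaque-associated double difference (-0.24) was -0.10 region-standardised, -0.032 as a mean over spots and -0.10 without clusters 12 and 13. The interferon list in 5xFAD-Dp16 over Dp16 (0.42) was 0.64 region-standardised and 0.25 at 20 CPM, and in 5xFAD over wild-type (0.37) it ranged from 0.17 without Hypothalamus to 0.89 at 20 CPM. T and B cell genes in 5xFAD-Dp16 over wild-type (-0.075) had 0.087 region-standardised, 0.056 as a mean over spots and 0.64 at 1 CPM. Without clusters 12 and 13, border macrophages in that pair (0.58) had -0.054, Ifi27l2a in Dp16 over wild-type (0.83) -0.20, Tagln there (0.60) -0.33, and the Igkc double difference (-2.57) 0.88. Oxt in 5xFAD over wild-type (-3.83) was 0.95 without Hypothalamus. The r of the Dp16 pairs (0.037) was -0.017 region-standardised and 0.075 at 20 CPM. That of the 5xFAD pairs (-0.010) was 0.11 region-standardised and 0.16 at 20 CPM.

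Genes higher in both Dp16 pairs (2) numbered 1 at 20 CPM, 1 region-standardised, 0 at 2-fold, 1 without cluster 21, 4 without Hypothalamus and 1 without clusters 12 and 13. Those lower (16) numbered 2 at 20 CPM, 4 at 2-fold and 9 without cluster 21. Genes higher in both 5xFAD pairs (47) numbered 27 at 20 CPM, 22 at 2-fold, 65 region-standardised and 64 without clusters 12 and 13, and those lower (4) 2 at 20 CPM and 2 without Hypothalamus. Shares of spots with Cst7 or Itgax in wild-type, Dp16, 5xFAD and 5xFAD-Dp16 were 0.845, 0.354, 30.2 and 25.8% unthinned and 0.0400, 0, 9.19 and 8.07% at 2 UMIs, and 19.1% in 5xFAD-Dp16 standardised by region.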

Other observations

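Plaque-associated microglial genes were not equally high in all regions. For 5xFAD over wild-type their relative median was highest in the region labelled Hypothalamus, led by Lhx1os and Arhgap36, at 1.57. For 5xFAD-Dp16 over Dp16 it was highest in the region labelled Thalamus, led by Prkcd and Shox2, at 1.33. The Hypothalamus value does not compare like tissue: expression cluster 15, with 213 spots under that label, had 228 spots in wild-type and 0 in 5xFAD. The lowest values were -0.25 in VL and 0.053 in CNU, a region with the striatal gene Penk among its leading genes, in the same order of pairs. The plaque mark was on 0 of 40 spots of VL in 5xFAD and 0 of 62 of CNU in 5xFAD-Dp16, but CNU had 0.82 for 5xFAD over wild-type with 0 of 30 spots marked. Differences between regions were not tested.

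Oligodendrocyte and myelin genes had a median of 0.27 in plaque over unmarked spots of 5xFAD-Dp16, with 22 of 24 members higher, against 0.020 and 15 of 24 in 5xFAD. Neighbour spots of 5xFAD-Dp16 had a similar 0.225 with 24 of 24 higher, so the value was not particular to marked spots. Ighm, an immunoglobulin heavy chain gene, was higher in plaque than in unmarked spots of both sections (1.39 and 1.20). Its levels over whole sections had log2 ratios of -0.28 and 0.40 in the 5xFAD pairs. Ighm was also among the genes leading expression cluster 9, beside the deep cortical layer marker Ccn2, so its level need not come from lymphocytes. Malat1, a nuclear non-coding RNA, was among the 47 genes at least 1.5-fold higher in both 5xFAD pairs (0.92 and 0.60). In sums not matched by region it was not higher in plaque spots. Malat1 was at 460 CPM in plaque and 503 CPM in unmarked spots of 5xFAD, and at 316 and 363 CPM in 5xFAD-Dp16. Ighm and Malat1 were singled out after their values had been seen. Cst7 had no UMI in 129 of 324 plaque spots of 5xFAD and 161 of 396 of 5xFAD-Dp16 at the deposited depth.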
